A study of Mus musculus with 4 samples.

How the data were processed

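The study profiled RNA of neural crest-derived cells from the gut of Wnt1-tdT mouse embryos at 11.5 days post coitum, with 2 libraries from the wavefront of the migrating cells and 2 from cells 1 to 1.5 mm behind it. Per the labels' protocols, tissue was dissociated with collagenase and dispase, tdT-positive cells were sorted, RNA was isolated with Trizol and libraries were made with the Illumina Nextera XT kit, which does not keep the strand. Per the submitters' processing notes, the tools were bcl2fastq 2.17, FastQC 0.11.9, STAR 2.5.2b, featureCounts and DESeq2, on GRCm38 (mm10). The annotation release and the settings for strand, multiple hits and overlapping genes are not given in the sources used here.

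A single table of 27606 rows was used, with Entrez and Ensembl identifiers and symbols. Per the file headers, the authors deposited CPM, the reads of a gene scaled to a common library total, for each library. Every CPM value was a whole multiple of the CPM of 1 read, so whole reads were recovered: 100% of values came out whole within 0.01 reads. This gave totals of 517000 and 452142 reads for trailing replicates 1 and 2 and 543070 and 260217 for wavefront replicates 1 and 2, where 1 read is worth 1.93, 2.21, 1.84 and 3.84 CPM and 3 reads, the floor used here, 5.80, 6.64, 5.52 and 11.5 CPM. The authors' deposited BaseMean column is a signal, the mean of reads divided by size factors (1.32, 1.23, 1.44 and 0.459 by least squares, in the same order of libraries). The deposited fold change and its standard error are on the log2 scale, per the file headers. The deposited Wald statistic is a score, the fold change over its standard error. The deposited p-value is the Wald test's and is not adjusted, and the Benjamini-Hochberg adjustment was made here. DESeq2 with a prior on fold changes, run on the recovered reads, came within 0.00954 of every log2 fold change of the authors' deposited table, so those folds are shrunken and smaller than the ones given here. The sign of the authors' folds is wavefront over trailing.

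Identifiers repeated on 428 rows were kept once, which left 27178 genes, of which 14589 had a read. Rows without a symbol (958, holding 1.27 to 2.51% of the reads of a library) were kept under their Entrez identifier, and mitochondrial symbols were set through the Ensembl identifier. Coordinates are those of GENCODE M21, which is on the same build, and gene names come from the table. Of 28 genes named by rule that passed the count test, 14 overlap another annotated gene and 3 overlap one with reads here. Some overlapping genes have no values here, such as Nefm, which overlaps Nefl by 5233 bases on the other strand. Without strand, reads of overlapping genes cannot be told apart.

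The design was written before the data were examined. For normalized values it set limma 3.58.1 with a mean-variance trend on log2(CPM + 1), for genes with a mean CPM above 1. Location was the only term. Once the unit was known, the count test that the design stated for recovered reads was added: edgeR 4.0.16, quasi-likelihood F test, TMM factors and filterByExpr with 10 reads, with standard errors taken from the fold change and the F statistic. Log2 fold changes of low genes can be smaller or larger in limma than in the count test. Kif5a was at -4.75 in limma against -6.48, and Tlx2 at -4.58 against -2.95. Scaled CPM are recovered reads over TMM-adjusted library sizes, given as mean ± SD over 2 libraries. The median log2 fold change of all genes was -0.35 in limma on CPM and 0.01 in the count test, and -0.20 in the count test scaled by library size alone, so gene changes are best read relative to these. The median in limma was -0.06 with DESeq2's size factors. DESeq2 1.42.0 was the other count tool, under R 4.3.3. All p-values are two-sided unless stated, adjusted p are Benjamini-Hochberg, and the threshold was 0.05. A gene with 1 to 3 reads in a group is given as a ratio of reads with an exact binomial counting interval (95%).

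The 25 gene lists (567 genes, 563 in the table; the others are not analysed here) were fixed before the data were examined. They cover crest progenitors, enteric neurons, glia and Schwann precursors, cell cycle, matrix, adhesion, guidance, Hox groups 1 to 5 and 6 to 13, Notch, Wnt, BMP with TGF-beta and Hedgehog, retinoic acid, glycolysis and hypoxia, dissociation stress, mitochondrial genome, ribosomal proteins, and 8 other cell types (gut mesenchyme, gut epithelium, mesothelium, endothelium, erythroid cells, leukocytes, muscle and cartilage, sensory and sympathetic neurons). Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives, where 2 or more members were tested. Of the mesenchyme list's 25 genes 8 are also in another list.

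The rule for named genes took the 10 largest rises and 10 largest falls among genes past the threshold with at least the median abundance and groups that do not overlap, leaving out model names; up to 4 members of each list by adjusted p; and fixed genes, among them Ret, Sox10, Ednrb and Elavl4. Some genes that this rule picks are not reported here, though they count in the totals. Limma passed no gene, so the first part was applied to the count test, a choice made after the data were seen. Other genes are named because they complete the count of a list, or, in the closing section, were chosen after their values were seen.

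The scripts were tested on 5 simulated tables of the real genes with 200 genes changed. All genes were given the same spread beyond counting error (a biological CV of 19.6%) in both groups. The changed genes were drawn from those past the filter of the count test, so the tables do not carry the full spread of the real data. The count test made 3.60 false calls per table (3.00% of its calls) over a mean of 5872 genes. Each of limma and edgeR found the changed list in 5 of 5 tables and the unchanged list in 0. All genes of the changed list fell 8-fold, and genes were drawn independently of each other. The list check was therefore easy to pass and cannot test the preset correlation between genes. Replicates were compared by a chi-square over genes, ribosomal RNA rows included. It was 2.45 per degree of freedom between the trailing libraries and 31.6 between the wavefront libraries, so no pair was 1 library deposited again. Alternatives were other scalings, filters, pseudocounts (0.1 and 5), thresholds, a replicate block, each library left out, DESeq2 and the authors' p-values. TMM scaling in limma, ribosomal RNA left out, and libraries thinned to 114972 reads were chosen after seeing the data.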

Results

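RNA was sequenced from neural crest-derived cells of the embryonic mouse gut at 11.5 days post coitum. These cells move down the gut and form the enteric nervous system, and the comparison asked how the mRNA of cells at the leading edge of that movement, the wavefront, differed from that of cells lying 1 to 1.5 mm behind it. Cells were sorted by flow cytometry for the red fluorescent reporter that marks neural crest derivatives in Wnt1-tdT mice. There were 4 libraries, 2 from the wavefront and 2 from the trailing position. The labels do not say whether replicates came from separate embryos or litters, so p-values measure only the spread between these libraries, which may be technical. Outside ribosomal RNA, trailing replicates 1 and 2 held 386540 and 330644 reads, wavefront replicate 1 held 452144 and wavefront replicate 2 held 114972. Genes with a read numbered 12368, 12321, 11949 and 10372 in the same order. Ribosomal RNA took 24.4% and 26.1% of the reads of the trailing libraries, 15.6% of wavefront replicate 1 and 55.5% of wavefront replicate 2. Reads assigned to Rn45s, the gene of the 45S precursor, were 46.2% of those of wavefront replicate 2 (95% exact binomial interval 46.0 to 46.4%). They were 12.5% of those of wavefront replicate 1 (12.4 to 12.6%). These reads were not divided into precursor and mature ribosomal RNA. Reads were not marked by molecular identifiers, so intervals here cover counting error only.

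Relative to other genes, the wavefront libraries held less RNA of most enteric neuron genes tested. They held more of 23 genes, which include 4 of 25 tested matrix genes and 1 of 13 tested adhesion genes. RNA per cell was not measured, and the mix of cells in the sorts may differ. In the count test, edgeR's quasi-likelihood test on reads recovered from the deposited values, Dbh, the enzyme that makes noradrenaline from dopamine, fell by 4.59 on the log2 scale, and Nefl, the neurofilament light chain, fell by 3.65. Cdh11, a mesenchymal cadherin, rose by 3.91, and Des, the muscle intermediate filament desmin, rose by 2.84. Ret and Ednrb, which mark enteric crest cells as a whole, did not pass. The count test called 100 of 5759 genes at a Benjamini-Hochberg adjusted p under 0.05, of which 23 were higher and 77 lower at the wavefront. Each of the 100 had both wavefront libraries on the same side of both trailing libraries, which 39.1% of the tested genes also did and chance gives for 33.3%. The test planned for CPM, limma on log2(CPM + 1), called 0 of 12519 genes, with 858 at an unadjusted p under 0.05 (134 higher, 724 lower) and a smallest adjusted p of 0.134. DESeq2 on the recovered reads called 13 of 4690 genes, and the p-values of the authors' deposited table, adjusted here by Benjamini-Hochberg, called 13 of 14589, all 13 among the 100. On simulated data in which all genes shared the same spread, limma found 0% of genes changed 8-fold and 0% of those changed 2-fold, edgeR 98.8% and 17.8%, and DESeq2 80% and 4.40%. The real wavefront libraries differed more from each other than the trailing ones (chi-square per degree of freedom 31.6 and 2.45). That chi-square kept the ribosomal RNA rows, whose share differed widely between the wavefront libraries. Across the genes tested by counts, with TMM scaling, the correlation was 0.859 between the wavefront libraries and 0.933 between the trailing ones. The shares found on simulated data may therefore not hold for the real data. The count test's number fell with either trailing library or wavefront replicate 1 left out, and rose without wavefront replicate 2. With scaling by library size alone the number was 73, of which 9 were higher and 64 lower.

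**Figure D1:**
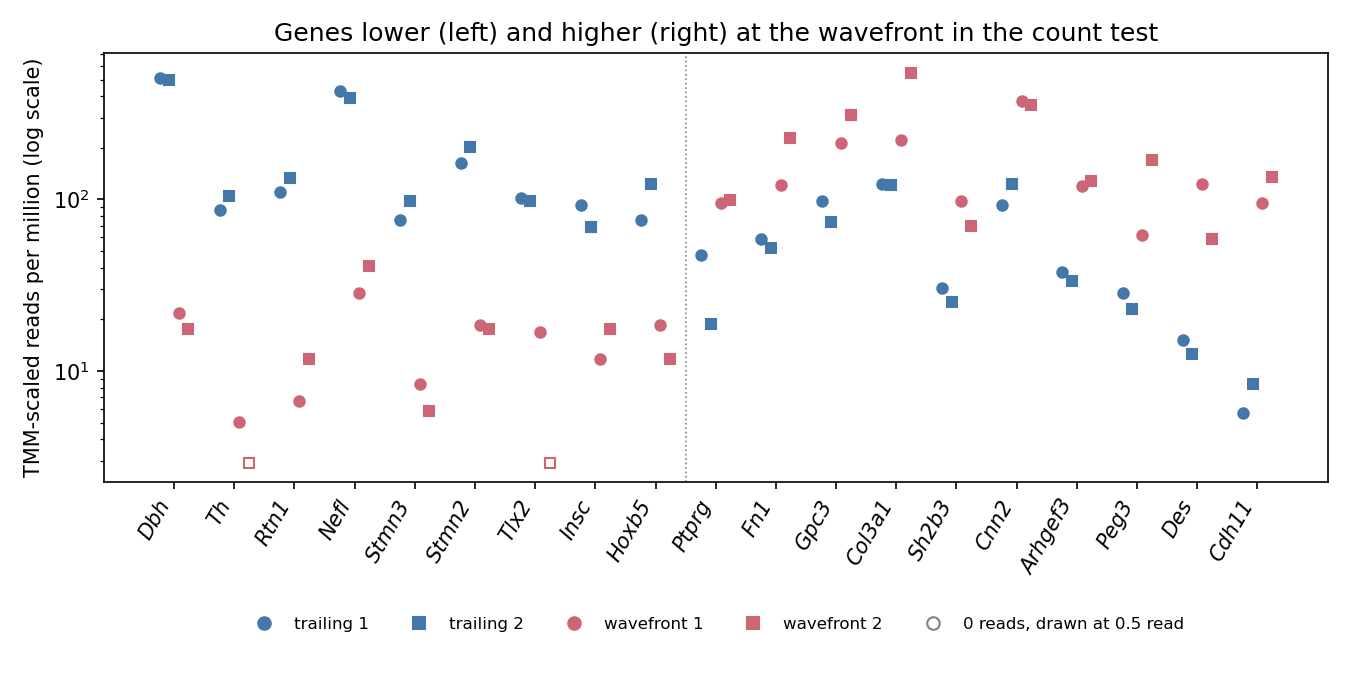
TMM-scaled CPM (log axis) in each of the 4 libraries for 9 of the 10 genes with the largest fall and the 10 with the largest rise in the count test, chosen by a fixed rule. Blue is trailing and red is wavefront, circles are replicate 1 and squares replicate 2, and open symbols mark libraries with 0 reads, drawn at the level of 0.5 read; the groups do not overlap for any of these genes.

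Most tested genes of the enteric neuron list were lower at the wavefront. In the count test 16 of its 26 tested members fell, 0 rose and 10 did not pass, and 21 fell when adjusted over the list alone. The median log2 fold change, wavefront over trailing, was -2.40, and 25 of the 26 members lay below 0. Dbh (chromosome 2, 27165233 to 27183200, GRCm38) had 505 ± 11.7 scaled CPM in trailing cells and 19.7 ± 3.04 at the wavefront (SD, n = 2 each; log2 fold change -4.59 ± 0.42 SE; edgeR with Benjamini-Hochberg, adjusted p = 7.58e-11). Th, the rate-limiting enzyme of catecholamine synthesis, had 96 reads in the trailing libraries and 3 at the wavefront, a scaled ratio of 24.4 (95% counting interval 8.10 to 120; edgeR adjusted p = 2.8e-07). Nefl (chromosome 14, 68083863 to 68089095) went from 407 ± 27.1 to 34.7 ± 8.73 scaled CPM (edgeR adjusted p = 3.52e-09). Rtn1, a reticulon of neuronal endoplasmic reticulum, fell by 3.90 ± 0.48 on the log2 scale, and of the microtubule regulators Stmn2 fell by 3.30 ± 0.40 and Stmn3 fell by 3.43 ± 0.51. The other members that fell were Mapt, Dcx, Prph, Slc18a3, Syt1, Cartpt, Elavl3, Gal, Tubb3 and Uchl1. Under 13 alternative settings Dbh, Nefl, Rtn1 and Stmn2 passed in all 13 and Stmn3 in 11, and Th passed in 12 of 12. Elavl4, a neuronal RNA-binding protein, did not pass, with 346 ± 23.4 scaled CPM in trailing cells and 165 ± 59.3 at the wavefront (edgeR adjusted p = 0.119). In limma 0 of the 37 members tested changed over all genes, and 22 fell when adjusted over the list alone. The list test (camera, Benjamini-Hochberg over the lists) gave an adjusted p of 9.5e-55 in the count test and 1.24e-22 in limma with the preset correlation. With an estimated correlation the adjusted p was 0.279 and 0.53.

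Reads of the listed markers of sensory and sympathetic neurons, which also derive from the neural crest, were few. Their list summed to 35 and 55 reads in the trailing libraries and 35 and 11 in the wavefront libraries. The catecholamine enzymes Dbh and Th were placed in the enteric neuron list, so these sums do not count them. Gata3, a transcription factor of sympathetic neurons, had 3 and 10 reads in the trailing libraries and 0 and 0 at the wavefront. Hand1, a transcription factor of sympathetic neurons and gut mesenchyme, went the other way, with 0 and 0 trailing reads and 1 and 3 wavefront reads, and Isl1 had 3 and 5 against 0 and 2. Eya1, with 28 and 36 trailing reads and 32 and 6 wavefront reads, was the 1 member past the filter of the count test and did not pass (log2 fold change -0.40 ± 0.37, edgeR adjusted p = 0.822). In limma 0 of 5 members passed over all genes and 1 fell when adjusted over the list alone, and the list test gave camera adjusted p = 0.69.

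Outside the enteric neuron list, the largest falls by the fixed rule included those of Tlx2, Insc and Hoxb5. Tlx2, a homeobox gene of enteric ganglia, had 54 and 47 reads against 10 and 0 (-2.95 ± 0.46, edgeR adjusted p = 2.36e-05). Insc, a regulator of spindle orientation, fell by 2.60 ± 0.46 (edgeR adjusted p = 0.000262). Under alternative settings Tlx2 passed in 11 of 13, Insc in 9 of 12 and Hoxb5 in 10 of 12.

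Of 52 genes of the extracellular matrix list, 25 were tested by counts: Tnc, Col3a1, Fn1 and Fbn2 rose, Postn fell and 20 did not pass, and 6 rose and 1 fell when adjusted over the list alone. Tnc, the matrix glycoprotein tenascin C, had 3 and 6 trailing reads against 31 and 13 at the wavefront (log2 fold change 2.69 ± 0.54, edgeR adjusted p = 0.00116). Fn1, fibronectin, rose from 55.6 ± 4.46 to 174 ± 75.6 scaled CPM (1.53 ± 0.34, edgeR adjusted p = 0.00468), and Postn, periostin, went from 125 ± 40.3 to 25.6 ± 11.4 (-2.09 ± 0.38, edgeR adjusted p = 0.000329). The list test gave camera adjusted p = 0.0549 in the count test and 0.000475 in limma, where it was 0.53 with an estimated correlation and 0.9 without wavefront replicate 2. Among 26 integrin and adhesion genes, 13 were tested by counts, of which Cdh11 rose and 12 did not pass; adjusted over the list alone, 2 rose and 4 fell (camera adjusted p = 0.684). Cdh11 (chromosome 8, 102632095 to 102785642) went from 7.03 ± 1.91 to 115 ± 27.3 scaled CPM (3.91 ± 0.48, edgeR adjusted p = 1.25e-07). Other genes of the fixed rule that rose were Cnn2, an actin-binding calponin (1.76 ± 0.32), Arhgef3 (1.77 ± 0.34), Gpc3, a heparan sulfate proteoglycan (1.55 ± 0.32), Sh2b3 (1.66 ± 0.37), Ptprg (1.52 ± 0.37) and the imprinted Peg3 (1.90 ± 0.41). Under 13 alternative settings of the count test Cdh11 passed in 13, Cnn2 in 11, Arhgef3, Gpc3, Peg3 and Fn1 in 8 each, and Sh2b3 and Ptprg in 6 each, while Tnc passed in 9 of 12. For 33 guidance and chemokine receptor genes, 12 were tested by counts and 0 passed, 2 rose when adjusted over the list alone, and the list test gave camera adjusted p = 0.243; in limma it was 0.0331, and 0.53 with an estimated correlation.

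The summed reads of gut mesenchyme markers were higher at the wavefront, most of all in wavefront replicate 2, the shallow library with the large ribosomal share. In wavefront replicate 1 Des and Col3a1 gave 73 and 132 of the list's 240 reads, and in wavefront replicate 2 they gave 10 and 94 of 188. The list summed to 259 and 251 CPM outside ribosomal RNA in the trailing libraries, 531 in wavefront replicate 1 and 1635 in wavefront replicate 2. Of its 25 genes 3 were tested by counts: Des and Col3a1 rose, over all genes and when adjusted over the list alone, and 1 did not pass (camera adjusted p = 1.37e-06, and adjusted p = 0.279 with an estimated correlation). Limma tested 18 members with 0 calls over all genes or over the list alone (camera adjusted p = 1.04e-11, 0.53 with an estimated correlation, and 0.117 without wavefront replicate 2). Des had 8 and 6 trailing reads against 73 and 10 (edgeR adjusted p = 1.35e-05). It passed in 9 of 13 alternative settings, but not without wavefront replicate 1, after thinning, in DESeq2 or by the authors' p-values. Col3a1 had 65 and 58 against 132 and 94 (edgeR adjusted p = 0.00406). It passed in 7 of 13 alternative settings. It did not pass without wavefront replicate 2, without either trailing library, with scaling by library size alone, in DESeq2 or by the authors' p-values. The erythroid list, red blood cell genes, had 2, 0 and 1 reads in the trailing libraries and wavefront replicate 1, and 113 in wavefront replicate 2, of which Hbb-y gave 67 and Hba-x 33 (limma camera adjusted p = 0.000279, 0.53 with an estimated correlation). Gut epithelium genes summed to 6 and 4 trailing reads against 26 and 15 (limma camera adjusted p = 6.98e-05, 0.53 with an estimated correlation). Mesothelium, endothelium, leukocyte, and muscle and cartilage lists did not pass the limma list test (adjusted p = 0.103, 0.142, 0.262 and 0.142).

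**Figure D2:**
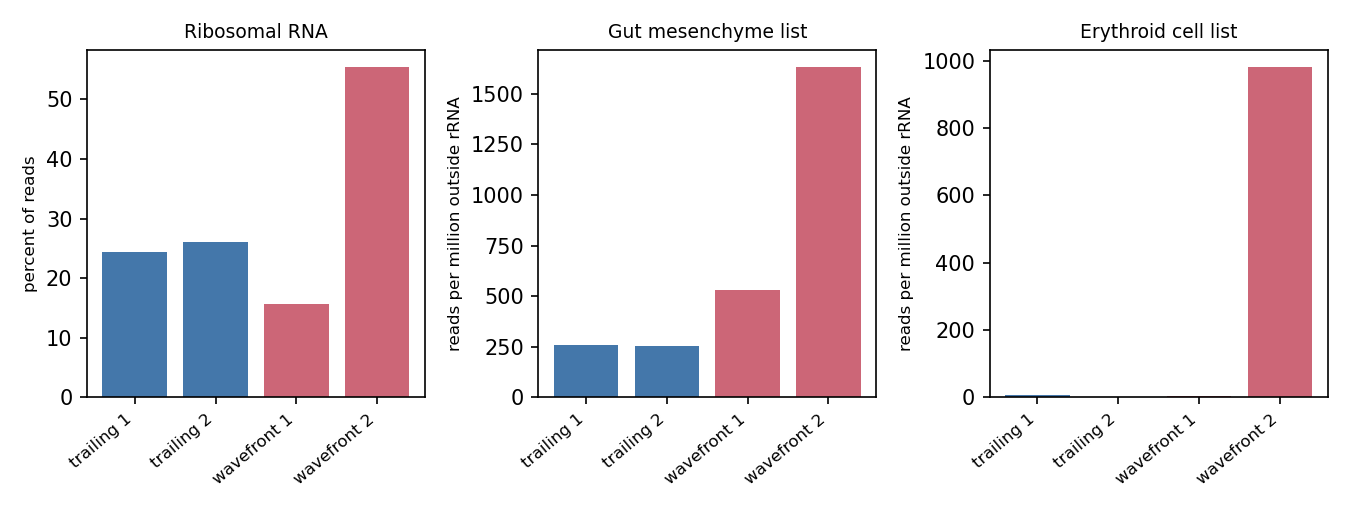
Bars give, for each of the 4 libraries (blue trailing, red wavefront), the percentage of reads from ribosomal RNA, and the summed CPM outside ribosomal RNA of the gut mesenchyme and erythroid lists. Wavefront replicate 2 has the highest bar in each panel, with 55.5%, 1635 and 983.

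Genes of crest progenitors showed no common direction. Of 13 tested by counts, 1 fell, 12 did not pass and 0 rose, and 1 rose and 1 fell when adjusted over the list alone. The median log2 fold change was 0.25 while the mean was -0.17 and the list test pointed down (camera adjusted p = 0.684). Ret, the receptor for the gut neurotrophic factor GDNF, had 864 and 545 trailing reads against 1413 and 155, with a log2 fold change of 0.25 ± 0.41 (edgeR adjusted p = 0.908). Ednrb, the endothelin receptor, was at -0.29 ± 0.33 (0.867) and Sox10, the crest and glial transcription factor, at -1.02 ± 0.45 (0.418), in the same edgeR test. In the glia and Schwann precursor list 6 were tested by counts: 2 fell, Postn among them, 4 did not pass, and 3 fell when adjusted over the list alone (camera adjusted p = 1.79e-05, and adjusted p = 0.425 with an estimated correlation). In limma, with 13 members tested, this list did not pass the list test (camera adjusted p = 0.0689).

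Among anterior Hox genes and retinoic acid genes, all changes that passed were falls. In Hox paralogue groups 1 to 5, 3 genes were tested by counts, of which Hoxb5 and Hoxd3 fell and 1 did not pass, with 2 fallen over the list alone. Hoxb5 (chromosome 11, 96303336 to 96306121) went from 99.7 ± 33.9 to 15.1 ± 4.80 scaled CPM (log2 fold change -2.54 ± 0.43, edgeR adjusted p = 0.000117). Hoxd3 changed by -1.33 ± 0.33 (edgeR adjusted p = 0.0168). Hoxd3 passed in 3 of 13 alternative settings and did not pass with any 1 library left out. The annotated span of Hoxd3 overlaps that of Hoxd4 by 17232 bases and Hoxb5 has an annotated antisense transcript, and the counting rule for such overlaps is not given in the sources used here. The list test gave camera adjusted p = 3.52e-05, and adjusted p = 0.279 with an estimated correlation. The summed reads of Hox groups 6 to 13 were 8 and 7 in the trailing libraries and 1 and 7 at the wavefront, below the filter of the count test (limma camera adjusted p = 0.594). All 8 tested genes of the retinoic acid list had log2 fold changes below 0, of which 2, Dhrs3 among them, fell over all genes and over the list alone and 6 did not pass. Dhrs3, a retinaldehyde reductase, had 38 trailing and 2 wavefront reads, a scaled ratio of 14.5 (95% counting interval 3.74 to 124; edgeR adjusted p = 0.00231), and passed in 7 of 12 alternative settings. This list gave camera adjusted p = 3.06e-05, and adjusted p = 0.425 with an estimated correlation.

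Among other signalling genes, single members moved. In the BMP, TGF-beta and Hedgehog list 7 were tested by counts: Tgfbi, a TGF-beta-induced matrix protein, rose, with 3 trailing and 27 wavefront reads (scaled ratio 11.8, 95% counting interval 3.63 to 60.8; edgeR adjusted p = 0.00403), and Id2, a BMP target, fell by 2.10 ± 0.50 (edgeR adjusted p = 0.0097), both also over the list alone, while 5 did not pass (camera adjusted p = 0.684). Of 18 glycolysis and hypoxia genes the glucose transporter Slc2a3 fell by 2.63 ± 0.60 (edgeR adjusted p = 0.00593) and 17 did not pass, with 1 risen and 1 fallen over the list alone (camera adjusted p = 0.413). Under alternative settings Tgfbi passed in 7 of 11, Id2 in 6 of 12 and Slc2a3 in 7 of 12. The 7 Notch genes, 5 Wnt genes and 10 dissociation stress genes tested by counts had 0 calls over all genes (camera adjusted p = 0.122, 0.684 and 0.413). Adjusted over the list alone, 1 Notch gene rose and 2 fell, and 0 of the Wnt and stress genes passed. The Wnt list had a median of 0.02, a mean of -0.18 and a list test that pointed down. The stress list had a median of -0.41 and pointed down by counts but up in limma (camera adjusted p = 0.601).

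Cell cycle genes, mitochondrial genes and ribosomal protein genes had 0 calls in the count test, over 40, 7 and 40 genes tested. The cell cycle list had a median log2 fold change of 0.28, with 31 of 40 members above 0 (camera adjusted p = 0.00841, and adjusted p = 0.568 with an estimated correlation); it was 0.0574 with scaling by library size alone, 0.174 without wavefront replicate 1 and 0.108 in limma, where the list test pointed up and the median was -0.02. Cdc6, a replication licensing factor, was at 1.04 ± 0.36 (edgeR adjusted p = 0.163). The 7 genes of the mitochondrial genome were all below 0, with a median of -0.68 (camera adjusted p = 0.000501, and adjusted p = 0.425 with an estimated correlation; 0.453 in limma), and 2 fell when adjusted over the list alone. Ribosomal protein genes had a median of -0.08 (camera adjusted p = 0.499).

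**Figure D3:**
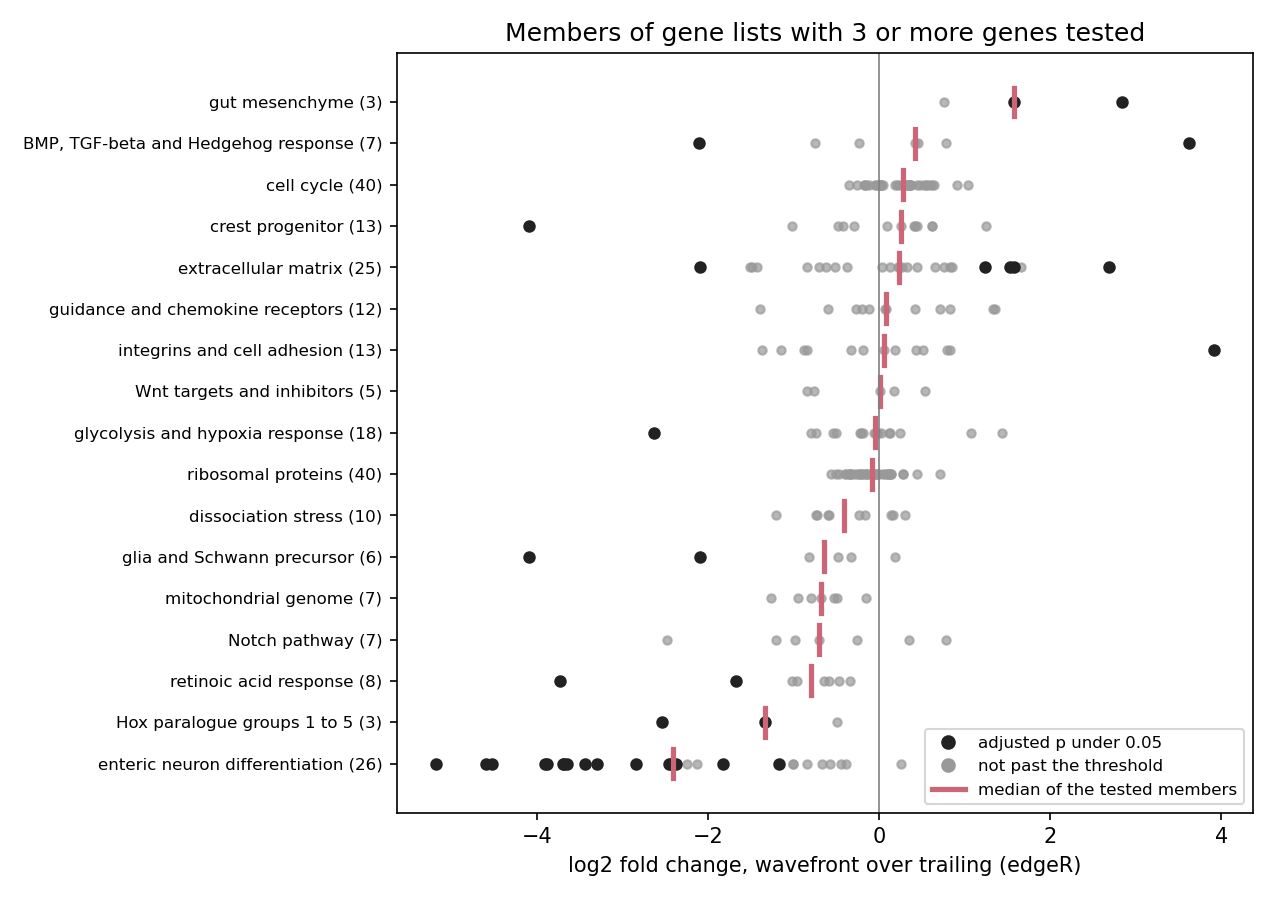
Log2 fold changes (wavefront over trailing, edgeR) of the members of each gene list with 3 or more genes tested by counts, the number tested in parentheses. Dark points passed an adjusted p of 0.05, grey points did not, and red bars are the medians, which run from -2.40 for the enteric neuron list to 1.58 for gut mesenchyme.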

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

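The counts of calls depended on the tool. Among the named genes and lists, 1 result passed the threshold in the direction opposite to its main test, the dissociation stress list of the count test. It pointed up without trailing replicate 2 (camera adjusted p = 0.045). With 1 library left out its adjusted p ranged from 0.000849, pointing down, to 0.183. Short of the threshold, some signs changed between settings. In the count test the log2 fold change of Ret ran from -0.62 to 0.82 and that of Sox5 from -1.63 to 0.32. The median of the crest progenitor list was -0.29 in limma and 0.25 in the count test. The count test's 100 genes became 63 at an adjusted p under 0.01, 13 in DESeq2, 13 by the authors' p-values and 24 after thinning; they ranged from 40 to 143 with 1 library left out, and a lone library is then assumed to vary like the other group. The limma count of 0 became 9 with median-of-ratios size factors, 46 with TMM, 4 without ribosomal RNA rows, 5 with no filter, 45 with the 10-read filter, 3 with a pseudocount of 5, 100 with edgeR, 13 with DESeq2 and 13 by the authors' p-values; it was 0 with any library left out. Calls adjusted over each list alone, summed over lists, were 34 in limma (0 to 89 with 1 library left out, 56 with edgeR) and 56 in the count test (41 to 65 with 1 library left out, 30 after thinning, 35 with DESeq2, 33 by the authors' p-values). Lists past the list test were 8 in limma and 0 with an estimated correlation (6 to 11 with 1 library left out); in the count test they were 7, with 11 under no filter, 0 with an estimated correlation, 0 with fry and 8 to 11 with 1 library left out. Deviations of same-numbered libraries correlated at 0.0724 across genes in the count test and 0.0230 in limma. With 2 libraries per group this cannot show whether same-numbered libraries were paired. With the replicate block the calls were 61 in the count test and 52 in limma. TMM, leaving out ribosomal RNA, edgeR and thinning were chosen after seeing the data; the cause of the differences was not tested, except that left-out libraries, stricter thresholds and thinning test fewer samples, calls or reads. Without wavefront replicate 2 the count test kept 16 of the 23 genes called higher and 62 of the 77 called lower; without wavefront replicate 1 it kept 12 and 24.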

Other observations

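Tests of scaling, of single libraries for sympathetic markers, of the mesenchymal and outside cells, of the neuron share, of imprinted genes and of other splits were chosen only after the result was seen.

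Other genes called by the count test lay outside the lists and were chosen after their values were seen. Kif5a, a neuronal kinesin, had 25 reads in the trailing libraries and 0 at the wavefront, at least 6.36-fold lower against a floor of 3 reads over the group. The nicotinic receptor subunits Chrna3 and Chrnb4 fell by 1.46 ± 0.33 and 1.68 ± 0.41 on the log2 scale (edgeR with Benjamini-Hochberg, adjusted p = 0.00547 and 0.0132), and Cck, the cholecystokinin peptide, by 2.05 ± 0.38 (0.00047). Of transcription factor genes, Onecut2 had 49 trailing reads against 2 (scaled ratio 18.7, 95% counting interval 4.90 to 159), St18 had 69 against 5 and Dlx2 fell by 1.73 ± 0.36. Among genes that rose, Ppp2r2b, a regulatory subunit of protein phosphatase 2A, had 2 and 4 trailing reads against 61 and 14 (3.94 ± 0.50), Stom, stomatin, 7 and 5 against 48 and 11 (2.63 ± 0.46), Gprc5c 6 and 5 against 39 and 13 (2.62 ± 0.48), and the atypical cadherin Fat1 29 and 28 against 57 and 38 (1.32 ± 0.35).

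The fall of the neuron list may reflect fewer or younger neurons at the wavefront, which was neither measured nor tested apart from the other explanations. Its median log2 fold change stayed at -2.39 or below under 4 scalings of the count test. A scaling moves all genes alike, and the median of all tested genes lay between -0.20 and 0.02 under these, so they could hardly bring the list to 0. The list thus fell relative to other genes, and no more is drawn from this. Its median was -2.31 without wavefront replicate 2, the shallow library. It was -2.34 after a trend on transcript length and GC content was removed (known for 100% of its tested members). The latter values argue against that library and sequence bias as whole causes. Sympathetic or sensory neurons in the trailing sort cannot be told apart from fewer or younger neurons at the wavefront. Reads of 11 sympathetic and sensory markers outside the enteric and mesenchyme lists pooled to 82 against 40, a depth-scaled ratio of 0.617 (95% counting interval 0.412 to 0.911). Wavefront replicate 1 and trailing replicate 1, however, did not differ beyond counting error (75.2 and 82.8 CPM outside ribosomal RNA, ratio 0.908, 0.544 to 1.52). The other libraries had 151 CPM (trailing replicate 2) and 52.2 CPM (wavefront replicate 2), and most of these reads were Eya1, whose groups overlapped in scaled CPM. The catecholamine enzymes Dbh and Th, members of the enteric list, were not among these markers. The marker reads therefore cannot tell whether the fall of Dbh and Th came from sympathetic neurons.

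The higher genes, matrix and mesenchymal ones among them, may come in part from cells outside the crest. In wavefront replicate 2 red blood cell transcripts, which a tdT sort should remove, were 352 times their trailing level (95% counting interval 95.3 to 2946), and mesenchyme list reads were 6.41 times it (5.20 to 7.90), so carried-over cells are a candidate source for that library. In wavefront replicate 1 mesenchyme reads were 2.08 times the trailing level (1.71 to 2.54), where the median gene called higher was at 3.29 times, and gut epithelium reads were 26 against 10, 4.12 times the trailing level (1.92 to 9.58). Of the 240 mesenchyme reads of that library Des gave 73 and Col3a1 132, so its rise lay mostly in these genes. Outside cells in that library cannot be told apart from expression by crest cells, because Col3a1 alone held 67.2% of the trailing mesenchyme reads and could hide a small share of mesenchyme. Whether a lower share of neurons raised every other gene was not decided. The crest progenitor list had a median log2 fold change of 0.25, against 1.85 for the genes called higher. Those genes were picked for their rise, and the scaling sets most genes near 0, so a gap was close to fixed in advance. A change of expression in crest cells stays open, untested.

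Imprinted genes were frequent among the calls. From a list of 46 imprinted genes, written after the calls had been seen, 23 were tested and 5 called (21.7%), against 95 of 5736 other genes (1.66%; one-sided Fisher exact p = 3.75e-05). Peg3 rose by 1.90 ± 0.41, and Meg3, Ndn, Nnat and Cdkn1c fell by 1.56 ± 0.34, 1.25 ± 0.32, 1.29 ± 0.33 and 1.23 ± 0.34 (edgeR with Benjamini-Hochberg, adjusted p = 0.00403, 0.00432, 0.0208, 0.0208 and 0.0405). Because the list was made with these calls known, the excess is only a hypothesis, and the 4 that fell may follow the neuronal genes.

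Of the 3 splits of the 4 libraries into 2 and 2, 1 gave as many genes in the count test as the real split, the real one itself with 100, and the highest of the other splits gave 0. So few splits cannot give a share under 0.05.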
